A study of Bacteria with 8 samples.

How the data were processed

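DNA was extracted from soil with a commercial soil kit and 16S rRNA gene libraries were prepared with an Illumina amplicon protocol, per the labels' protocols. The deposited table gives whole read counts for each OTU and plot, and a second deposited table gives the taxon names of each OTU from domain to species. How the authors trimmed, clustered and filtered the reads, removed chimeras and assigned taxa is not given in the sources used here. The 8 plots were assigned to 2 locations, hospital or university, from the sample labels. A name for pooled blanks in the deposited sample list had no matching counts here, so blanks were not analysed here. Cultures that the series describes were not analysed here.

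The deposited counts comprised 625 OTUs, 10 of them without a read, and 54522 reads in all, from 4890 to 10323 per plot. The smallest count above 0 was 2 and no cell held 1 read, so a listed 0 may hide a single read. Reads were summed per phylum (32 with a read), family (287) and genus (410). Names that were placeholders or repeated a higher rank, which covered 51.4% of reads at genus level, were kept as separate entries under their nearest named rank and are called unnamed or uncultured. No OTU was assigned to plastids, mitochondria or a domain other than Bacteria, so none was left out. Of the taxon names, 1 class stood in more than 1 phylum and 2 orders in more than 1 class, so families and genera were summed within their phylum.

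Differences between locations were tested with edgeR 4.0.16 in R 4.3.3, using glmQLFit with its default dispersion and glmQLFTest on the deposited counts, with total-count scaling for phyla and TMM scaling for other ranks. Taxa with a read in at least 3 plots and at least 20 reads in all were tested, and Benjamini-Hochberg adjusted p-values under 0.05 passed. Log2 changes are university over hospital. Where a location had no reads, a lower bound on the fold was set against 3 reads per library, since a fitted change then depends on the prior count. Relative abundance per plot carries a Wilson 95% confidence interval, which covers counting error only, because amplicon reads are not independent molecules. Richness and Shannon diversity (natural log) are means of 100 random draws of each plot to 4890 reads. These values and the summed shares of the lists were compared with exact two-sided permutation tests over 70 assignments of the plots. Composition was compared by PERMANOVA on Bray-Curtis dissimilarity of relative abundance over all 35 splits. The closest pair of libraries, university plots 7 and 8, had a dissimilarity of 0.347, against 0.0814 expected from read sampling alone, which leaves out variation from extraction and PCR. All 8 libraries were treated as separate samples, per the labels.

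The tests, the alternatives, the 14 lists of genera and the rule for naming taxa were set before the data were examined. The 14 lists are hospital-associated opportunists, gut-associated genera, skin-associated genera, nitrifiers, nitrogen fixers, antibiotic-producing actinomycetes, endospore formers, dry-soil genera, hydrocarbon and xenobiotic degraders, predatory and myxobacterial genera, photosynthetic cyanobacteria, DNA-kit contaminants, halophilic and alkaliphilic genera, and plastid and mitochondrial reads. Named phyla have a mean share of at least 1% or passed the test. Families named are the 8 most abundant and up to 8 per direction that passed, and genera the 12 most abundant and up to 12 per direction that passed. With fewer than 5 genera passing, the 5 with the smallest p in each direction are named too, said not to pass. Up to 4 OTUs per direction that passed would be named. From lists past or near the threshold up to 4 members with the most reads are named, and from the opportunist list up to 8.

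Alternatives were other scalings, DESeq2 1.42.0 with poscounts size factors, limma 3.58.1 on centred log-ratios with a pseudocount of 0.5, no filter, edgeR's filterByExpr, other dissimilarities and ranks, other scales for the lists, and each plot left out in turn. Shares, diversity and composition were computed in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6. The tests were tested on simulated data with the depths of these plots, in 20 simulations per rank. Among 24 phyla, edgeR called 75% of those changed 16-fold and 27.5% of those changed 4-fold. Among 146 genera it called 5% of those changed 16-fold, among 137 families 12%, and among 183 OTUs 0.5%. The simulated dispersions were estimated without location, so real differences may have raised them and lowered these rates. With no change, a false call came in 3 of 20 simulations for families, 1 for phyla and 0 for genera and OTUs. Beside changed taxa it came in 5 of 20 for families, 1 for phyla, 1 for genera and 0 for OTUs. Simulated taxa were drawn independently of each other, so these rates may understate false calls where taxa vary together. In the real counts, 11 of the 35 splits of the plots, the real one included, called 1 or more phyla, and 3 called 2 genera. With 200 of 615 OTUs changed 8-fold, the composition test gave a p under 0.05 in 44 of 50 simulations, and in 1 of 50 with no change.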

Results

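Bacterial 16S rRNA genes were sequenced from 8 soil samples, called plots here, 4 labelled as from an Indian hospital and 4 from an Indian university. The comparison addresses whether the soil bacterial communities of these locations differ. Each plot gave 1 library. Hospital plots 1, 2, 5 and 6 held 4890, 7187, 6733 and 10323 counted reads. University plots 3, 4, 7 and 8 held 5802, 6470, 6666 and 6451. Reads fell into 615 operational taxonomic units (OTUs, groups of similar 16S sequences), of which 312 were found in 1 plot only and carried 8.98% of all reads. Another 20 OTUs were found in all 8 plots and carried 32.4%. Means are given ± SD with n = 4 plots per location unless stated otherwise, and relative abundance is the percent of a plot's reads. Because each plot was sampled once, p-values set differences against the spread between these plots. In edgeR, DESeq2 and limma that spread is estimated partly from all taxa tested together, not from each taxon alone. The labels do not say whether more than 1 hospital or university was sampled. The kind of location therefore cannot be told apart from the site, and the p-values do not extend to other hospitals or universities.

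Proteobacteria led the communities of both locations, with 23.4% ± 10.2 of reads in hospital plots and 29.4% ± 4.95 in university plots. Acidobacteriota, a phylum of mostly slow-growing soil bacteria, held 16.5% ± 3.78 and 15.7% ± 8.62. Actinobacteriota held 9.18% ± 5.12 at the hospital and 9.51% ± 4.97 at the university, and Firmicutes 8.24% ± 4.91 and 9.81% ± 2.83. Bacteroidota took 3.10% ± 2.13 and 6.47% ± 1.54 of reads, Chloroflexi 5.15% ± 3.11 and 4.12% ± 2.10, and Entotheonellaeota 3.74% ± 1.26 and 5.45% ± 4.09. Myxococcota, which include social predatory bacteria, made up 3.41% ± 2.54 and 3.86% ± 2.23, and Gemmatimonadota 3.34% ± 2.40 and 2.87% ± 1.05. Planctomycetota held 2.39% ± 1.40 and 2.36% ± 0.817, Armatimonadota 2.04% ± 2.30 and 2.31% ± 2.22, and the nitrite-oxidising Nitrospirota 1.55% ± 1.52 and 1.54% ± 1.31. Cyanobacteria were the only phylum of the 24 tested to pass edgeR's quasi-likelihood test, and they were more abundant in the hospital plots. For the other 12 phyla above 1%, edgeR's adjusted p lay between 0.963 and 0.995.

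**Figure D1:**
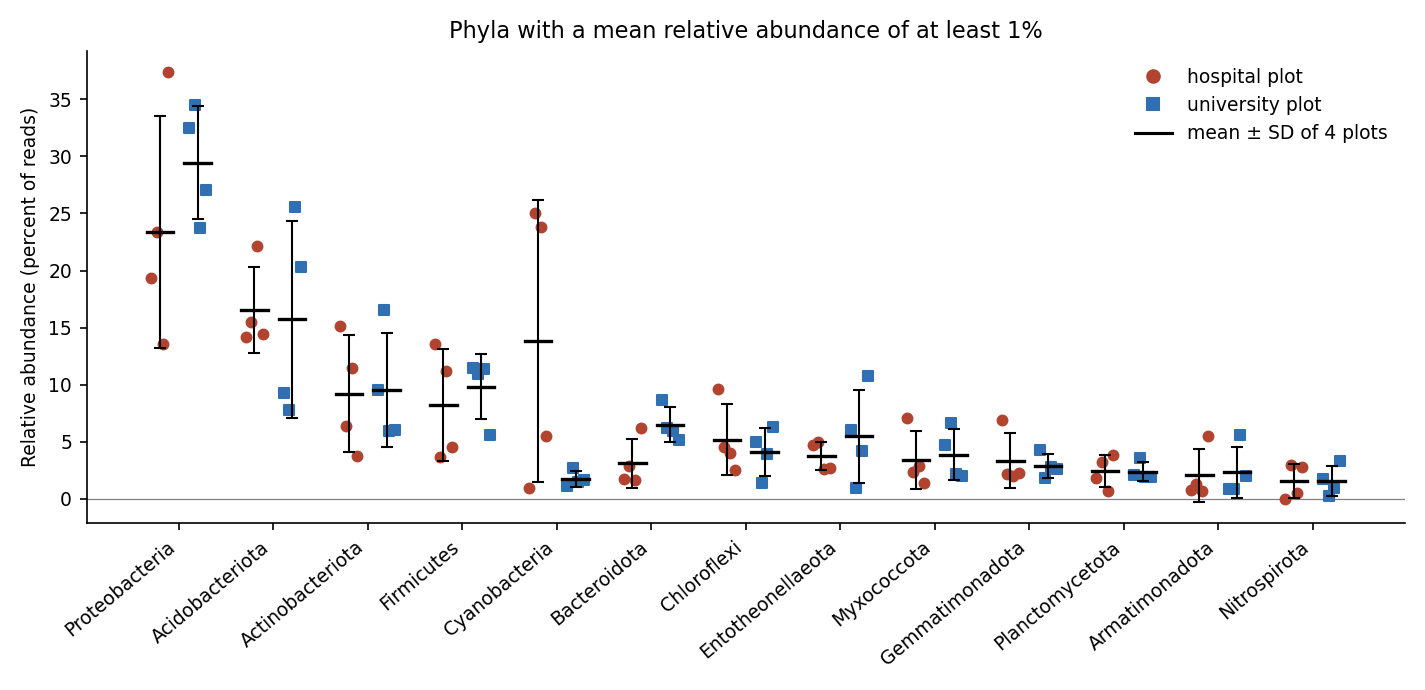
Relative abundance (percent of reads, vertical axis) of the 13 phyla with a mean of at least 1%, with 1 point per plot and the mean ± SD of the 4 plots of each location. Cyanobacteria spread from 0.961% to 25.0% over the hospital plots, while the 4 university plots lay between 1.07% and 2.69%.

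Cyanobacteria, photosynthetic bacteria that form crusts and mats on soil, held 13.8% ± 12.4 of reads in hospital plots and 1.71% ± 0.695 in university plots. Their log2 change, university over hospital, was -3.01 ± 0.64 (SE), with an adjusted p of 0.000136 by edgeR. The hospital plots differed widely among themselves. Plot 2 held 25.0% (Wilson 95% confidence interval 24.1 to 26.1), plot 5 held 23.8% (22.8 to 24.9) and plot 6 held 5.47% (5.05 to 5.93), whereas plot 1 held 0.961% (0.724 to 1.28), below the share of each university plot, although its interval overlaps that of university plot 3 (0.835 to 1.37). Thus 3 of 4 hospital plots lay above every university plot. The edgeR p-value also depends on the spread of the taxa tested beside the phylum. Among the summed lists, nearly the same reads gave -3.01 ± 0.86 (SE), with an edgeR adjusted p of 0.0488. The exact two-sided permutation test, which uses these plot shares alone, gave p = 0.143. For the phylum, limma on centred log-ratios gave a log2 change of -2.47 with an adjusted p of 0.586. Over the 6 other settings with all plots the adjusted p ranged from 0.00011 to 0.586 and 5 passed, and with 1 plot left out all 8 fits passed.

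At genus level the 2 entries that passed edgeR's test were both cyanobacteria, and both were read only in hospital plots 2, 5 and 6. Stanieria_PCC-7437, a unicellular genus of the family Xenococcaceae, held 5.72%, 0.847% and 0.756% of reads there. Its mean of 1.83% ± 2.62 over the hospital plots was at least 38.6-fold higher than the level that 3 reads per library would give in the university plots (edgeR adjusted p = 0.0146). Desmonostoc_PCC-7422, a filamentous member of the nitrogen-fixing Nostocaceae, held 0.320% to 2.88% in these plots, at least 24.8-fold higher over the 4 hospital plots (edgeR adjusted p = 0.0405). Both bounds allow for read counting only, not for the spread between plots. The exact two-sided permutation test of the plot shares gave p = 0.143 for each of these 2 genera. All 10 cyanobacterial genus entries with enough reads for the test had a higher fitted abundance in hospital plots under each of the 4 scalings, and the other 8 did not pass over all genera. These entries are parts of the called phylum and the scalings use the same counts, so their agreement is not separate support. The largest of the 10 entries, a group of Oxyphotobacteria without a genus name, held 4.15% ± 3.82 and 0.801% ± 0.770 (edgeR adjusted p = 0.199). Phormidium_IAM_M-71, a filamentous mat former, held 0.871% ± 0.688 in hospital plots and 0.205% ± 0.244 in university plots. Both calls ended with total-count scaling, with limma and with edgeR's newer dispersion estimate (adjusted p = 0.0540 and 0.0795), and edgeR's filterByExpr left both genera untested. Both also ended when university plot 3, 4 or 7 was left out, and Desmonostoc_PCC-7422 ended without university plot 8 (edgeR adjusted p = 0.0725). Without hospital plot 2, 5 or 6 both were read in too few plots to be tested.

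**Figure D2:**
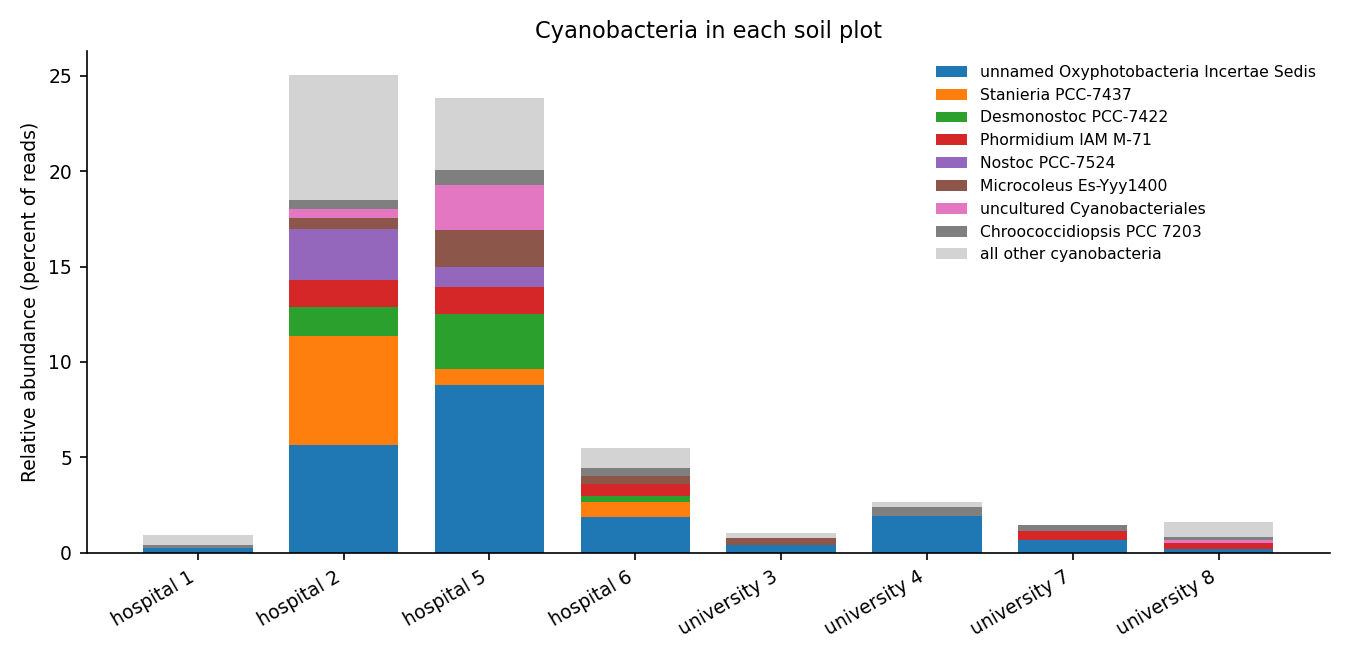
Relative abundance of cyanobacteria (percent of reads, vertical axis) in each plot, stacked by the 8 genus entries with the most reads and all others. Stanieria_PCC-7437 and Desmonostoc_PCC-7422 appear in hospital plots 2, 5 and 6, and hospital plot 1 resembles the university plots at 0.961%.

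The 12 most abundant genus entries carried 45.2% of reads on average, and none of them passed edgeR's test with its filter. Without the filter 2 of them passed, Subgroup_10 (adjusted p = 0.0258) and uncultured Cellvibrionaceae (adjusted p = 0.00909). Bacillus, a genus of endospore formers, had the highest mean over all 8 plots, with 7.01% ± 3.96 in hospital and 6.19% ± 2.36 in university plots. Subgroup_10 of the acidobacterial family Thermoanaerobaculaceae held 8.60% ± 6.23 and 1.80% ± 1.14, and each hospital plot exceeded every university plot (exact two-sided permutation p = 0.0286, which chance gives a genus in 2 of 70 assignments). Its log2 change was -2.37 ± 0.77 (SE), with an edgeR adjusted p of 0.143. An entry of Rhizobiales without a genus name held 3.42% ± 1.58 and 7.19% ± 4.30, and Pseudomonas, metabolically versatile soil and water bacteria, 2.34% ± 2.57 and 4.77% ± 3.16. Candidatus_Entotheonella, known for a rich secondary metabolism, held 3.68% ± 1.33 and 4.63% ± 3.45, and an unnamed entry of Myxococcaceae 3.19% ± 2.37 and 3.33% ± 2.21. Further acidobacteria were the entry listed as 44889, at 2.92% ± 1.78 and 4.83% ± 2.89, and Subgroup_5, at 1.02% ± 1.39 and 3.51% ± 3.67. An unnamed gammaproteobacterial entry was the most even of the 12, with 3.28% ± 0.274 and 3.60% ± 0.208, and KD4-96 of the Chloroflexi held 2.21% ± 2.79 and 2.16% ± 0.971. Uncultured Cellvibrionaceae, a family with many polysaccharide degraders, held 5.33% ± 9.57 and 0.510% ± 0.486. Hospital plot 6 alone set that difference, since without it the log2 change moved from -3.61 to 0.10.

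Several entries were read in university plots only, and none of these passed edgeR's test. Subgroup_9 of the Acidobacteriota and A21b of the Proteobacteria were found in all 4 university plots and no hospital plot, at 0.509% ± 0.414 and 0.381% ± 0.231. An unnamed entry of Peptostreptococcaceae, anaerobes common in the gut, averaged 0.767% ± 1.27 over the university plots, with 2.67% in plot 3. Clostridium_sensu_stricto_1 averaged 0.539% ± 0.596 and an unnamed entry of Alcaligenaceae 0.386% ± 0.298, each in 3 university plots. Amphiplicatus, at 0.251% ± 0.173, and Ilumatobacter, at 0.0723% ± 0.0572, were each read in 3 hospital plots and no university plot. These 5 entries of the university side and the next 5 of the hospital side, which also include Subgroup_10, the uncultured Cellvibrionaceae and the Oxyphotobacteria group, had edgeR adjusted p-values between 0.143 and 0.345. With DESeq2, 6 genera passed, among them Subgroup_9, A21b, the Peptostreptococcaceae entry and Clostridium_sensu_stricto_1.

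No family passed edgeR's test among 137, with 10 at an unadjusted p under 0.05, while DESeq2 called 6 and limma 0. The most abundant families were Bacillaceae, with 7.13% ± 3.91 at the hospital and 6.59% ± 2.62 at the university, Thermoanaerobaculaceae, made up of the Subgroup_10 reads, and the family-level Rhizobiales entry given above. Entotheonellaceae followed with 3.74% ± 1.26 and 5.45% ± 4.09, Pseudomonadaceae with 1973 reads in all, most of them from Pseudomonas, and Cellvibrionaceae with 5.38% ± 9.53 and 1.53% ± 1.48. The entry 44889 and the unnamed gammaproteobacterial entry complete the 8 largest, with the values given above. Among the 183 OTUs tested, edgeR called 0, with 23 at an unadjusted p under 0.05, DESeq2 called 9 and limma 0.

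Genera that include hospital-associated opportunists were sought first among the 14 lists. They held 5.84% ± 2.51 of reads in hospital plots and 9.39% ± 4.39 in university plots, a difference that did not pass (exact two-sided permutation test, p = 0.2, adjusted p = 0.433). Without university plot 4 the difference of 3.55 percentage points was 1.82. Only 7 of the 34 genera listed were detected. Pseudomonas had the most reads, with the values given above, followed by Mycobacterium, at 2.39% ± 0.858 and 1.81% ± 1.33, and Burkholderia-Caballeronia-Paraburkholderia, at 0.887% ± 0.400 and 1.82% ± 1.87. In hospital plots the mean of Mycobacterium was slightly above that of Pseudomonas, at 2.34%. Nocardia was read in 1 hospital and 1 university plot, and Aeromonas likewise with 6 reads. Acinetobacter was read in 2 university plots with 48 reads and Chryseobacterium in 1 with 23. None of the 3 genera tested passed edgeR, adjusted over the list alone or over all genera. A genus name does not identify a species, and soil species of these genera are common. Gut-associated genera were represented by Christensenellaceae_R-7_group alone, with 8 reads in 2 university plots (exact p = 0.429). Skin-associated genera were represented by Kocuria and Cutibacterium, with 27 reads in hospital plots and none in university plots (exact p = 0.143). Without hospital plot 1, which held all Kocuria reads, their difference moved from -0.129 to -0.0291 percentage points, and Cutibacterium is also listed as a DNA-kit contaminant.

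None of the 13 lists with a detected member passed the exact permutation test, and 0 had an unadjusted p under 0.05. The smallest p that 70 assignments allow is 0.0286. A list that alone reached it, as skin-associated genera did without hospital plot 6, had an adjusted exact p of 0.371. The adjusted test therefore could not call a single list alone, and 0 passing lists do not show that the locations were alike. edgeR on the list sums called 1 of 12, the photosynthetic cyanobacteria, at an adjusted p of 0.0488. This list holds 52 OTUs against 54 in the phylum Cyanobacteria, so the call repeats that of the phylum and is not a separate result. That list held 13.8% ± 12.4 and 1.71% ± 0.695 (exact p = 0.143), with 2 of its 10 tested genera passing, adjusted over the list alone as well as over all genera. Without hospital plot 1 its difference was -16.4 percentage points (exact p = 0.0286, adjusted 0.186). Nitrogen-fixing genera other than cyanobacteria had the smallest unadjusted exact p, with 0.202% ± 0.256 at the hospital and 0.805% ± 0.373 at the university (exact p = 0.0571), although 6 lists shared the smallest adjusted p of 0.433. Over genus-assigned reads this list and that of DNA-kit contaminants each had an exact p of 0.0286 (adjusted 0.186). That total includes the cyanobacteria with a genus name, which held 8.50% ± 7.79 of all reads in hospital and 0.785% ± 0.229 in university plots. Their higher share lowers that of other lists in hospital plots. The nitrogen-fixing genera with the most reads were Azotobacter (87 reads), Cupriavidus (70), Devosia (55) and Azohydromonas (35). Genera often met as contaminants of DNA kits held 1.05% ± 0.365 and 2.63% ± 1.53 (exact p = 0.0857), mostly Burkholderia-Caballeronia-Paraburkholderia with 707 reads and Acidovorax with 174, which also occur in soil. Without university plot 8 their difference of 1.58 percentage points was 0.874. Endospore formers were nearly equal, at 8.03% ± 4.95 and 8.01% ± 2.79 (exact p = 0.971). Of their 5 tested genera 1 passed adjusted over the list alone, Clostridium_sensu_stricto_1 at 0.0295 by edgeR, and 0 passed over all genera. Predatory and myxobacterial genera held 0.730% ± 0.499 and 1.16% ± 0.220 (exact p = 0.171). Their difference of 0.433 percentage points was 0.654 without hospital plot 1 (exact p = 0.0286, adjusted 0.186) and 0.274 without hospital plot 6. This list left out the larger entry of Myxococcaceae without a genus name, which held 3.19% ± 2.37 and 3.33% ± 2.21. Hydrocarbon and xenobiotic degraders held 4.95% ± 2.21 and 7.95% ± 5.34 (exact p = 0.314). Their largest members were Mycobacterium (2.39%) and Pseudomonas (2.34%) in hospital plots, and Pseudomonas (4.77%) in university plots. Nitrifiers, led by Nitrospira, held 1.77% ± 1.29 and 1.89% ± 1.28 (exact permutation test, adjusted p = 0.971). Antibiotic-producing actinomycetes, with the most reads in Streptomyces, held 1.34% ± 0.958 and 1.45% ± 1.97 (exact p = 0.943). In university plots Nocardia, read in 1 of them, had a higher mean than Streptomyces (0.680% against 0.457%). Dry-soil genera, led by Rubrobacter, held 2.88% ± 3.60 and 2.30% ± 0.977 (exact p = 0.971), with a difference that turned from -0.573 to 1.21 percentage points without hospital plot 1, and halophilic and alkaliphilic genera 0.229% ± 0.238 and 0.679% ± 1.23 (exact p = 0.886). No OTU was assigned to plastids or mitochondria. No tested genus of the other lists passed adjusted over the list alone, and the gut and skin lists had none with enough reads for the test.

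Location was associated with 22.3% of the variation in Bray-Curtis dissimilarity between plots, against a mean of 14.3% over all 35 splits of the plots, with a permutation p of 0.0571. The mean dissimilarity was 0.676 between plots of different locations, 0.638 among hospital plots and 0.596 among university plots. Distances to the group centroid did not separate the locations (exact permutation p = 0.543). University plots 7 and 8 were the most alike, at 0.347, and shared 95 OTUs. Hospital plot 1 was closer to university plot 3, at 0.554, than to any hospital plot. In all, 228 OTUs were found at both locations, 187 in hospital plots only and 200 in university plots only. A single OTU, of Candidatus_Alysiosphaera, was found in all 4 hospital plots and no university plot, and 3 OTUs, of Subgroup_9, A21b and Candidatus_Solibacter, in the reverse pattern. These 4 were named after their values were seen, and 3 of the 35 splits gave as many such OTUs, with 8 in the highest other. OTUs found in at least 3 plots of one location and none of the other numbered 17, and 3 of the 35 splits gave as many. Leaving out hospital plot 1 or university plot 4 brought the p of the composition test to 0.0286, the smallest that 35 splits allow.

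**Figure D3:**
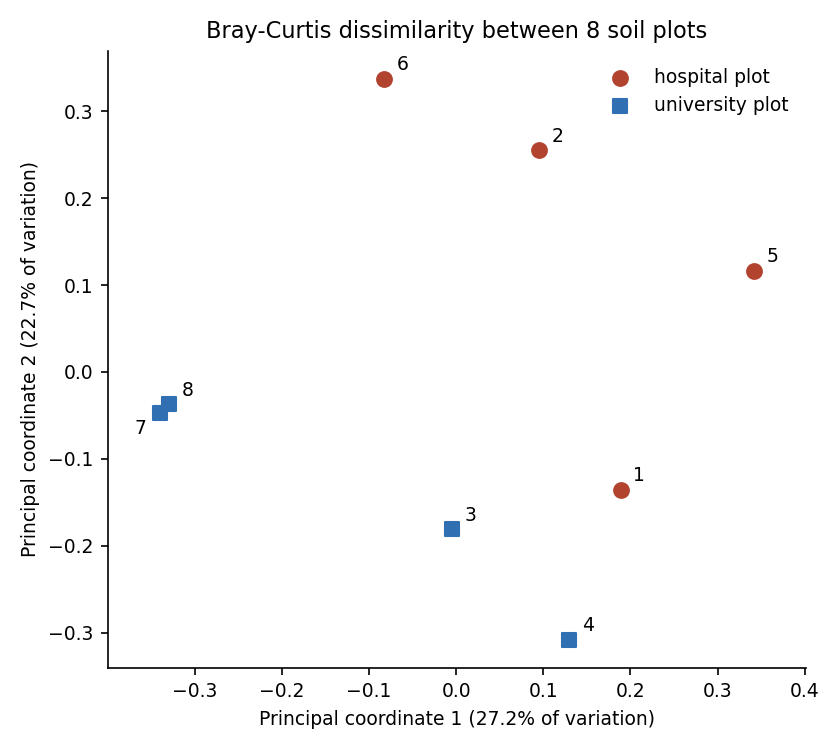
Principal coordinates of the Bray-Curtis dissimilarity between the 8 plots, with 1 point per plot labelled by plot number and the share of variation on each axis (27.2% and 22.7%). University plots 7 and 8 lie together, and hospital plot 1 lies nearer to university plots 3 and 4 than to hospital plots 2 and 6.

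OTU richness at the depth of the smallest plot was 177 ± 31.6 in hospital plots and 179 ± 15.4 in university plots, a difference of 1.25 OTUs (exact two-sided permutation test, p = 0.886). Hospital plot 1 had the fewest OTUs, at 140, and hospital plot 6 the most, at 207. Shannon diversity was 4.26 ± 0.198 and 4.39 ± 0.198 (exact two-sided permutation test, p = 0.343). Both differences were smaller than the spread between plots of one location. The direction of the richness difference changed with thinning and with the plots included.

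**Figure D4:**
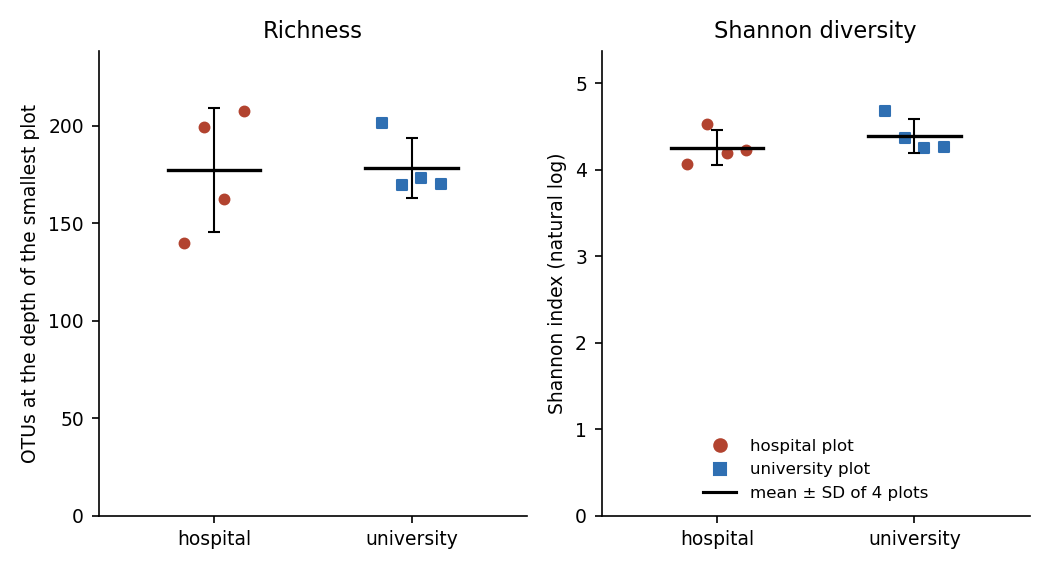
OTU richness (left, OTUs at the depth of the smallest plot) and Shannon index (right, natural log), with 1 point per plot and the mean ± SD of 4 plots per location. Hospital plots spread from 140 to 207 OTUs and university plots from 169 to 202.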

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

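The refits of the cyanobacterial test and the split counts at an unadjusted p were chosen only after the results were seen, whereas the counts past the threshold over other splits were planned. A plot is listed below when its gap to the nearest of the other plots of its location exceeded Dixon's 95% critical share of their whole range. Of 105 such sets of 4 plots, 14 met this. Chance flags about 1 in 20 sets of normally distributed values, but its rate for these skewed and partly overlapping shares was not tested.

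The higher share of cyanobacteria in hospital plots was weighed against technical explanations. Without the cyanobacterial OTUs that have no genus name of their own, 39.8% of the phylum's reads, among which chloroplast reads could be hidden, the log2 change of the phylum was -3.55 ± 0.72 (SE, edgeR adjusted p = 5.03e-05) against -3.01 ± 0.64 with them, which argues against chloroplast reads as the whole cause. The single cyanobacterial OTU with the most reads held 17.8% of the phylum's reads, which argues against 1 dominant OTU. Without it the log2 change was -2.90 ± 0.65 (edgeR adjusted p = 0.000395), though leaving out so small a share could move it little. Chance could not be excluded, since 11 of the 35 splits gave 1 or more phyla, with 1 phylum in the real split and 3 in the highest other. The exact permutation p of the shares was 0.143 and 1 hospital plot lay below all university plots. A difference between the locations stays open as a hypothesis, untested beyond these plots, alongside patchy growth of cyanobacteria in single plots.

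At genus level chance could not be excluded either, since 3 of the 35 splits gave as many as the 2 genera of the real split, and the highest other gave 2. For families and OTUs edgeR called 0 in all 35 splits, with 0 in the real split and 0 in the highest other, so these counts exclude nothing. At an unadjusted p under 0.05 the real split had 10 families and 23 OTUs, where 10 and 2 of the 35 splits gave as many, so chance could not be excluded. The highest other split, plots 1, 3, 4 and 5 against the rest, gave 24 and 37. DESeq2 called 6 families and 9 OTUs past the threshold, and limma 0 and 0.

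Hospital plot 6 held 19.7% of its reads in the uncultured Cellvibrionaceae, and so 19.7% in the family Cellvibrionaceae, against at most 1.22% in the other hospital plots. It also held 5.46% Armatimonadota, against at most 1.25%. Hospital plot 1 stood apart with 6.93% Gemmatimonadota, with 8.22% in dry-soil genera and with 0.429% in skin-associated genera, against at most 2.29%, 1.77% and 0.0594% in the others. Hospital plot 2 held 5.72% Stanieria_PCC-7437 and 6.43% Pseudomonadaceae, against at most 0.847% and 1.59%. Hospital plot 5 held 22.1% Acidobacteriota, against at most 15.5%.

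University plot 3 had the highest richness of its location, at 201.5 OTUs against at most 173.1. It also held 2.52% in halophilic and alkaliphilic genera and 2.67% in the unnamed Peptostreptococcaceae, against at most 0.201% and 0.217%. University plot 4 held 3.57% Planctomycetota, against at most 2.10%. University plot 8 held 5.58% Firmicutes, against at least 10.9% in the others.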

How the results depend on the processing

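The newer dispersion estimate of edgeR was chosen after the data were seen, and all other alternatives were planned. Keeping plastid, mitochondrial and non-bacterial OTUs gave no value of its own, because none was listed. No paired analysis was possible because the plots of both locations share no replicate number. The 1 phylum called became 0 with limma on centred log-ratios and stayed 1, Cyanobacteria, under the other scalings, tools and filters. Families went from 0 to 6 with DESeq2 and 4 without a filter, OTUs from 0 to 9 and 4, and genera from 2 to 6 and 5. Genera fell to 0 with total-count scaling, limma, filterByExpr, which left both called genera untested, and the newer dispersion. With 1 plot left out, edgeR called 1 to 2 phyla, 0 to 2 families, 0 to 2 genera and 0 to 2 OTUs. The second phylum was Dependentiae, called without hospital plot 6. The families were called without hospital plot 1 (2) or 2 (1), and the OTUs without hospital plot 1 (1) or 2 (2). Richness, university minus hospital, reversed to -0.5 without thinning, and ranged from -11.2 to 11.3 with 1 plot left out, negative without hospital plot 1 (-11.2), university plot 3 (-6.40) or hospital plot 5 (-3.69). Shannon diversity kept its direction, from 0.0365 to 0.225. Location was associated with 21.5% to 27.5% of the variation in composition with 1 plot left out, at permutation p-values from 0.0286 to 0.143. It passed without hospital plot 1 (27.4%) or university plot 4 (27.5%). Other dissimilarities and ranks gave 17.2% to 21.1%, none past the threshold, at permutation p-values from 0.0571 to 0.2. The number of lists past the threshold went from 0 to 1 with edgeR on list sums, namely the cyanobacteria, nearly the same reads as the called phylum. It stayed 0 otherwise, where the adjusted exact test could not call a single list alone. With 1 plot left out, the difference between locations took both signs for 5 of 13 lists, namely nitrifiers (-0.365 to 0.569 percentage points), antibiotic producers (-0.831 to 0.591), endospore formers (-1.52 to 1.73), dry-soil genera (-1.35 to 1.21) and halophilic genera (-0.162 to 0.677). The difference in degraders fell from 3.01 to 0.865 without university plot 4, and that in gut genera rested mostly on university plot 3 (0.103% of its reads). The log2 change of uncultured Cellvibrionaceae, -3.61, ranged from -4.72 to 0.10 with 1 plot left out, and reversed without hospital plot 6 (0.10). The log2 changes of the 3 called taxa stayed negative in every setting that tested them. For the 2 called genera this direction follows from having no reads in university plots. For the 13 taxa that were called or had the smallest p, under settings with all plots, 56 log2 changes kept direction and side of the threshold, 6 newly passed and 7 no longer did; with 1 plot left out, 75 kept both and 7 no longer passed. With 1 plot left out, differences in phylum shares moved by less than the larger location SD, as they must with 4 plots. Of the 13 phyla above 1%, 9 took both signs, such as Acidobacteriota (-4.09 to 1.84 percentage points). Cyanobacteria (-16.4 to -8.38) and Bacteroidota (at least 2.63) kept theirs. So did Proteobacteria (2.73 without hospital plot 5 to 10.7 without hospital plot 6, against 6.02). Firmicutes did too (0.0378 without hospital plot 2 to 3.35 without hospital plot 1, against 1.57). The median log2 change of all phyla moved by -0.37 with TMM and -0.23 with DESeq2, and that of genera by 0.18 with total-count scaling. Except where a genus was no longer tested, the cause was not tested. At 4890 to 10323 reads per plot and 4 plots per location, changes of 16-fold in single genera were mostly missed in simulated data (5% called).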

Other observations

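The tests of depth and richness and the look at taxon names were chosen only after the data were seen.

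Rarer phyla, chosen after their values were seen, also varied between plots. Dependentiae, thought to live inside protists, were read in all 4 university plots and in 1 hospital plot, with 0.657% ± 0.473 and 0.0436% ± 0.0872 of reads (exact permutation test, p = 0.0571, edgeR adjusted p = 0.359). Bdellovibrionota, which include predators of other bacteria, held 1.08% ± 0.429 in university and 0.455% ± 0.337 in hospital plots, and Verrucomicrobiota 1.43% ± 0.612 and 0.573% ± 0.505, each with an exact permutation p of 0.0857. Patescibacteria, with small genomes and cells, held 0.681% ± 0.801 and 0.686% ± 0.244. Zixibacteria were read in 2 hospital plots only, with 1.54% of reads in hospital plot 6. Elusimicrobiota reached 2.80% in the same plot.

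Uncultured Vicinamibacteraceae, listed under Acidobacteriota with an order name of another phylum, held 1.57% ± 0.381 in the 4 university plots and 0.417% in hospital plot 2, the only hospital plot with its reads. Of the settings run, it passed only without hospital plot 2, which leaves no hospital reads (edgeR). It was named after its values were seen.

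The split of the plots that separated composition most was not the location. Plots 1, 3, 4 and 5 against 2, 6, 7 and 8 accounted for 23.8% of the variation in Bray-Curtis dissimilarity against 22.3% for location. The gap was wider for genera, at 28.5% against 18.9% for location (PERMANOVA p of location = 0.171). For families it was 28.3% against 18.9% (PERMANOVA p of location = 0.2). The same split gave the highest number of OTUs found in at least 3 plots of one side and none of the other, with 31 against 17 for location and a median of 9 over the 35 splits.

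The number of OTUs per plot and the number of reads correlated over the 8 plots (Pearson's r = 0.704, exact permutation p = 0.0406, Spearman's rho = 0.539, exact permutation p = 0.175). Without hospital plots 6 and 1, farthest from the median depth, r was -0.117 (exact permutation p = 0.758), so the relation rests on those plots. Thinning to 4890 reads removed at most 3.10% of a plot's listed OTUs. OTU numbers ran up to 4556 while 625 OTUs were listed, and no count of 1 was listed. Rare OTUs may therefore have been removed before the counts were deposited. Thinning would then understate the effect of depth, so it cannot decide whether the number of reads caused the differences in richness. The correlation of reads and OTUs was the only relation across plots that was computed.

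The order, family and genus names 44889 and 44581 are bare whole numbers. Read as spreadsheet day numbers they give month 11, day 24 and month 1, day 20. The first covers 3 OTUs of Blastocatellia with 2154 reads, 3.95% of the total, and the second 1 OTU of Anaerolineae with 7 reads. Names of the form 11-24 occur in bacterial taxonomies, and a spreadsheet conversion was not tested here.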
